A study of Mus musculus with 30 samples.

How the data were processed

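The measurement was RNA sequencing of polyadenylated RNA from bilateral punches of the nucleus accumbens, a reward and pain relay of the ventral striatum, of male C57BL/6J mice. Each of the 30 libraries came from 1 animal. The mice had a spared nerve injury (SNI), a model of neuropathic pain in which branches of the sciatic nerve are cut and another is left intact, or a sham operation. From 4 weeks after surgery they received injections 2 times a day for 3 weeks, of saline, of tianeptine at 30 mg/kg or of desipramine at 15 mg/kg. The 6 groups were taken from the sample labels. The design text gives sham mice on saline as the control.

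Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to the mouse genome build mm10 with HISAT2, handled with SAMtools and counted per gene with featureCounts, and their versions are not given in the sources used here. The strand setting and the annotation release used for counting are not given there either, so counts of genes that overlap another gene on the opposite strand are less certain. The deposited count table holds a whole-number count for each of 55401 gene IDs in each library. The deposited FPKM table holds the same counts scaled by the library total and by the whole span of each gene, introns included. No column of per-sample values was left unused. The numbering in the library names falls into 2 sets, read here as 2 rounds of library preparation or sequencing. The first set holds 24 libraries, replicates 1 to 4 of every group, with 24.5 to 37.7 M (mega) counts each. The second holds 6 libraries, replicates 5 and 6 of the saline and tianeptine groups, with 98 to 120.7 M. No desipramine library is in the second set. Within the first set the library numbers run in unbroken blocks by group. If any step of handling followed this order, its effect could not be told apart from that of the group. No pair of libraries of a group was a near copy of the other, since the smallest chi-square per degree of freedom between their counts was 7.51.

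Gene symbols, IDs and positions came from GENCODE M21 on mm10. Of the gene IDs, 54349 matched exactly, 792 matched without the version number and 260 had no match. The unmatched IDs held 0.051% of all counts. The test used edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. Genes were kept by filterByExpr, which left 23736 genes with 99.925% of all counts. Libraries were scaled by the trimmed mean of M values (TMM), and a robust quasi-likelihood model was fitted with 1 coefficient per group and 1 for the library set. It had 23 residual degrees of freedom, a median of 3.14 prior degrees of freedom and a common biological coefficient of variation of 17.5%. Each of 13 comparisons was a contrast of this model, tested 2-sided and adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Adjusted p values of genes are from this edgeR test unless another tool is named. Log2 fold changes are given with their standard error (SE). Levels are CPM, a gene's counts per M counts of its library scaled by TMM, as mean and standard deviation (SD) over the libraries of a group. Intervals of a difference have a confidence level of 95%.

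The 41 gene lists cover transmitter and receptor systems, stress, immune, metabolic and clock genes, markers of accumbens and neighbouring cell types, and signs of RNA quality. They were fixed before the data were examined, as were the comparisons, the alternatives listed last except the 5 added ones, and the rule for named genes. Lists with at least 5 tested members were tested with camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera compares the list with all other genes, and its p values were adjusted over the 41 lists within each comparison. Each test was repeated with the correlation estimated from the data. The test fry, which asks whether the members move one way without comparing them with other genes, was run on the same lists. A list score is the mean over members of log2 CPM, each centred on its mean over all libraries.

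The genes named per comparison were, among those passing, up to 6 higher and 6 lower of smallest p and up to 4 higher and 4 lower of largest log2 fold change with a mean log2 CPM of at least 1. For each list with a camera call or a passing member, up to 4 members of smallest p could be named. Where fewer than 6 genes passed in a direction, the genes of smallest p filled the place and are said not to have passed. Oprm1, Slc6a2, Adra2a, Drd1, Drd2, Fos, Bdnf and Gria1 could always be named. Predicted gene models were counted and not named. The values of some genes that the rule names are not reported here. Slc6a2, the noradrenaline transporter that desipramine blocks, had 28 counts over all libraries and was not tested.

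The test was checked on simulated counts with known changes, drawn gene by gene from the means, library set effects and dispersions of these libraries. Genes in such counts do not move together with tissue as in the real libraries, so the shares below hold only without that. Per comparison, the test called 3 to 13 genes that had not been changed. For SNI against sham on saline it recovered 52.2% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 92.4% of those changed 3-fold. For tianeptine against saline in SNI the shares were 53.7%, 80.6% and 87.9%. They were 40.3%, 67.2% and 86.4% for desipramine against saline in SNI, 26.9%, 62.7% and 92.4% for the interaction of tianeptine with surgery, and 32.8%, 59.7% and 72.7% for that of desipramine. Counting error is small at these depths for genes with many counts, and the precision of each comparison is then set by 4 to 6 animals per group. For genes with few counts it adds to the spread.

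The alternatives were DESeq2 size factors (DESeq2 1.42.0), the DESeq2 Wald test, limma-voom, no filter beyond 1 count, and a filter of a CPM of at least 1 in at least 4 libraries. Others were no library set term, replicates 1 to 4 alone, a fit of only the groups compared, replicate number as a block, 2 surrogate variables (sva 3.50.0) and each library left out in turn. The FPKM table was tested with limma as log2 values with a pseudocount of 1 or 0.1. The 5 alternatives added after seeing the data were 3 tissue scores as covariates, used for genes and for lists, and 3 that leave out pairs of libraries with outlying scores. Each count was also set among 100 splits of the same libraries into groups of the same sizes, the real one included. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.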

Results

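Gene expression in the nucleus accumbens was measured in 30 male mice that had a spared nerve injury (SNI) or a sham operation and then received saline, tianeptine or desipramine. Tianeptine is an atypical antidepressant that activates the mu-opioid receptor, and desipramine is a tricyclic antidepressant that blocks noradrenaline reuptake. There were 5 sham mice on saline, 6 on tianeptine and 4 on desipramine, and 5 SNI mice on saline, 6 on tianeptine and 4 on desipramine. Total counts ran from 24.5 to 120.7 M per library in the sham saline group, 27.8 to 106.9 M with tianeptine and 24.8 to 35 M with desipramine. In SNI they ran from 27.5 to 98 M on saline, 26.4 to 107 M with tianeptine and 25.7 to 28.5 M with desipramine. All libraries above 37.7 M belong to the second library set, which holds no desipramine library.

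Markers of neighbouring tissue differed between libraries of 1 group. The score of neurons of the septum, preoptic area and hypothalamus, which lie beside the accumbens, was 1.52 in SNI desipramine replicate 2 and 1.46 in replicate 3, against 0.47 in replicate 1 and -0.23 in replicate 4. The score of medium spiny neurons, the main cell type of the accumbens, was -2.22 in replicate 2, -0.8 in replicate 3, -0.32 in replicate 1 and 0.39 in replicate 4. Its mean was 0.29 ± 0.16 (SD, n = 5) in sham saline and -0.74 ± 1.1 (SD, n = 4) in SNI desipramine. The choroid plexus score reached 3.15 in sham tianeptine replicate 6, with a group mean of 0.55 ± 1.42 (SD, n = 6). In sham saline replicate 3, the fibroblast and meninges score was 2.72, the interferon score 0.98 and the peripheral immune cell score 1.86, the highest of their group. Sham saline replicate 2 had the lowest share of mitochondrial counts of its group, 0.991% against 1.1% to 1.85%, and 73.2 mitochondrial tRNA counts per M against 213 to 254.

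**Figure D1:**
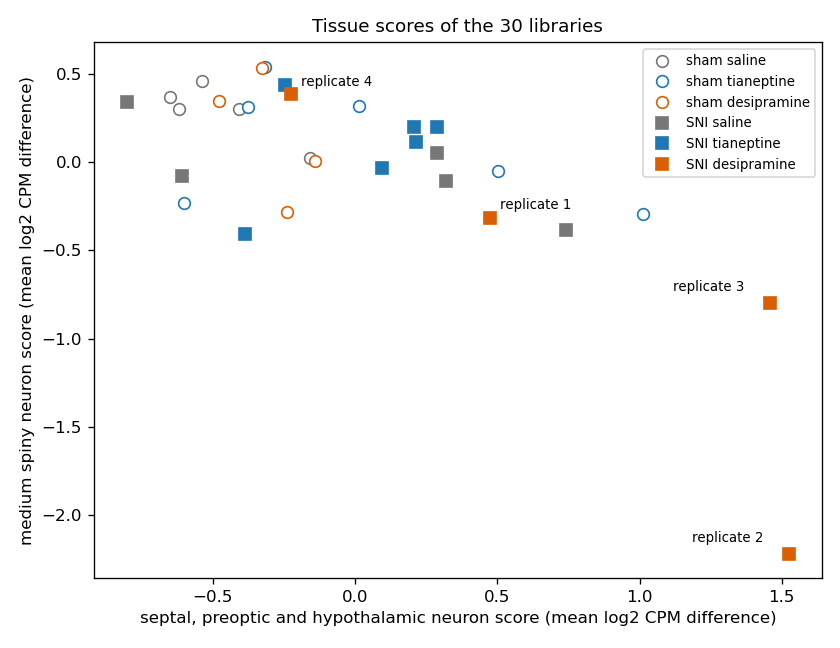
Scores of marker lists (mean centred log2 CPM of the members) in each library, by group, with open circles for sham and filled squares for SNI. The SNI desipramine libraries, labelled by replicate, run from -2.22 to 0.39 in the medium spiny neuron score and from -0.23 to 1.52 in the septal, preoptic and hypothalamic score.

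SNI was compared with sham in mice on saline to ask what the nerve injury changed in the accumbens. Genes of blood vessels were among those of smallest p and were lower in SNI, but no gene passed the test. Lamc1, a laminin chain of the vessel basement membrane, differed by -0.37 ± 0.07 (log2 fold change ± SE) and Kdr, the VEGF receptor of endothelial cells, by -0.54 ± 0.13, both with an adjusted p of 0.404. Flt1, another VEGF receptor, differed by -0.48 ± 0.12, the endothelial adhesion genes Pecam1 by -0.54 ± 0.15 and Cdh5 by -0.64 ± 0.18, and Pdgfrb, the PDGF receptor of pericytes, by -0.44 ± 0.11. Mean Kdr was 17.3 ± 2.42 CPM (SD, n = 5) in sham and 12 ± 1.91 CPM (SD, n = 5) in SNI.

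Of 18 endothelial markers, all were lower in SNI, 12 of them past the threshold when adjusted over the list alone (camera adjusted p = 3.28e-12, and adjusted p = 0.477 with an estimated correlation). All 13 mural cell markers were lower, 10 past the threshold adjusted over the list alone (camera adjusted p = 5.43e-09, and adjusted p = 0.316 with an estimated correlation). Fibroblast and meninges markers were lower in 19 of 20, with a median log2 fold change of -1.40 (camera adjusted p = 4.88e-07, and adjusted p = 0.666 with an estimated correlation), and Col1a1, a collagen chain, differed by -1.15 ± 0.38. Interferon response genes were lower in 30 of 34 (camera adjusted p = 4.8e-07, and adjusted p = 0.668 with an estimated correlation). The antigen presentation genes Cd74 and H2-Aa differed by -2.05 ± 0.70 and -2.24 ± 0.74, with mean Cd74 at 10.2 ± 13.8 CPM (SD, n = 5) in sham and 2.66 ± 1.33 CPM (SD, n = 5) in SNI. These lists move with sham saline replicate 3, whose fibroblast score was 2.72 and peripheral immune score 1.86. Without sham saline replicates 2 and 3, 7 of 15 list calls were kept, endothelial and mural among them, while fibroblast and meninges genes no longer passed (adjusted p = 0.358) and the interferon response list turned to higher (adjusted p = 0.196).

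Metallothionein 2 (Mt2), a metal-binding stress gene, was 0.46 ± 0.09 higher in SNI, Gstz1, an enzyme of tyrosine breakdown, 0.26 ± 0.06 higher and Dynlrb1, a dynein light chain, 0.24 ± 0.05 higher, none past the threshold. Immediate early genes, which mark recent neuronal activity, were lower in 27 of 31 (camera adjusted p = 0.00564, and adjusted p = 0.67 with an estimated correlation), while Fos itself differed by -0.09 ± 0.54. The call of the immediate early genes was lost with tissue scores as covariates (adjusted p = 0.279) and without sham saline replicates 2 and 3 (adjusted p = 0.677). The mu-opioid receptor gene Oprm1 differed by 0.29 ± 0.15, and the dopamine receptor genes Drd1 and Drd2 by -0.42 ± 0.35 and -0.39 ± 0.32. No gene passed with edgeR, with 2311 at an unadjusted p under the threshold where 1187 are expected by chance. DESeq2 called 1 gene and limma-voom 0.

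Tianeptine was compared with saline in SNI to ask what 3 weeks of the drug changed after injury. The genes of smallest p were Ppp1r15b, a regulator of protein synthesis, at 0.26 ± 0.05 (adjusted p = 0.788), and the histone methyltransferase genes Prdm2 at 0.20 ± 0.05 and Setd1b at 0.23 ± 0.06. The linker histone gene Hist1h1c differed by -0.65 ± 0.16 and the peroxisomal gene Acaa1b by -0.95 ± 0.22. Mt2 was lower at -0.32 ± 0.09, opposite in sign to its value in SNI against sham, and the saline SNI libraries enter both values. None of these passed.

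Nuclear-encoded genes of oxidative phosphorylation were lower with tianeptine in 69 of 74 (camera adjusted p = 1.23e-10, and adjusted p = 0.874 with an estimated correlation), with a median of -0.07. Immediate early genes were higher in 29 of 31, with a median of 0.31 (camera adjusted p = 1.06e-05, and adjusted p = 0.874 with an estimated correlation). Among them, Nr4a3, a nuclear receptor induced by activity, differed by 0.78 ± 0.38 and Fos by 0.69 ± 0.52. Circadian clock genes were higher in 16 of 19, with 1 past the threshold adjusted over the list alone (camera adjusted p = 2.47e-05, and adjusted p = 0.601 with an estimated correlation). Nr1d2, which encodes the clock repressor REV-ERB beta, differed by 0.24 ± 0.07 and Ciart, a repressor of the CLOCK and BMAL1 pair, by 0.26 ± 0.11. Oprm1 differed by 0.00 ± 0.15. Of 10 list calls, 4 were kept without SNI saline replicate 3, 6 without SNI saline replicate 4 and 5 without SNI tianeptine replicate 4, where the immediate early genes no longer passed (adjusted p = 0.056). With edgeR 0 genes passed, 681 were at an unadjusted p under the threshold, and DESeq2 called 1 gene and limma-voom 0.

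In sham mice, tianeptine was compared with saline to give the drug's effect without injury. Ciart had the smallest p, at 0.56 ± 0.11 (adjusted p = 0.714), with 11 ± 1.01 CPM (SD, n = 6) on tianeptine and 7.47 ± 1.22 CPM (SD, n = 5) on saline, and each tianeptine library lay above each saline library. Next came vessel genes, all lower: Cldn5, the tight junction gene of the blood-brain barrier, at -0.68 ± 0.16, Lamc1 at -0.30 ± 0.07 and Kdr at -0.50 ± 0.13. Fcrls, a microglial receptor gene, differed by -0.29 ± 0.07 and Olfml3, another microglial gene, by -0.38 ± 0.09. All 18 endothelial markers were lower, 7 past the threshold adjusted over the list alone (camera adjusted p = 1.4e-12, and adjusted p = 0.32 with an estimated correlation). Microglial markers were lower in 20 of 21, 3 of them past it adjusted over the list alone (camera adjusted p = 8.56e-09, and adjusted p = 0.378 with an estimated correlation). All 20 choroid plexus and ependyma markers were higher, 7 past it adjusted over the list alone (camera adjusted p = 1.02e-06, and adjusted p = 0.569 with an estimated correlation), and they move with sham tianeptine replicate 6, whose choroid plexus score was 3.15. Sham saline replicate 3, with a fibroblast score of 2.72 and a peripheral immune score of 1.86, is among the controls here, and without sham saline replicates 2 and 3 the list calls kept were 6 of 14, these 3 lists among them. With edgeR 0 genes passed, 1623 were at an unadjusted p under the threshold, and DESeq2 called 1 gene and limma-voom 0.

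Averaged over both surgeries, tianeptine gave 0 genes with edgeR, 1126 at an unadjusted p under the threshold, 1 with DESeq2 and 0 with limma-voom. Ciart differed by 0.41 ± 0.08 (adjusted p = 0.577), Nr1d2 by 0.21 ± 0.05 and Arntl, which encodes BMAL1, by -0.26 ± 0.08. Clock genes were higher in 14 of 19, with 4 higher and 1 lower past the threshold adjusted over the list alone (camera adjusted p = 0.000421, and adjusted p = 0.639 with an estimated correlation). Microglial markers were lower in 19 of 21 (camera adjusted p = 2.21e-09, and adjusted p = 0.639 with an estimated correlation), with Fcrls at -0.24 ± 0.05. The test of whether tianeptine acted differently in SNI and sham gave 0 genes, 997 at an unadjusted p under the threshold, and 0 with DESeq2 and with limma-voom. In it, Lamc1 differed by 0.41 ± 0.10 and Flt1 by 0.61 ± 0.17 (both adjusted p = 0.989).

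Desipramine was compared with saline in sham mice. Spred2 and Spred3, which encode inhibitors of the RAS-ERK pathway, were 0.31 ± 0.05 and 0.50 ± 0.09 higher (both adjusted p = 0.0599), and the neuropeptide precursor gene Vgf, which is induced by neurotrophins, was 0.50 ± 0.09 higher (adjusted p = 0.0998). Mean Vgf was 319 ± 5.5 CPM (SD, n = 4) on desipramine and 225 ± 32.7 CPM (SD, n = 5) on saline, and mean Spred3 79.8 ± 6.47 CPM (SD, n = 4) and 55.6 ± 2.4 CPM (SD, n = 5). For both genes, each desipramine library lay above each saline library. Mpp2, a synaptic scaffold gene, was 0.32 ± 0.06 higher, Ciart lower at -0.61 ± 0.13 and Ddit4, a stress gene that restrains mTOR, lower at -0.38 ± 0.11. Oprm1 differed by 0.42 ± 0.16 (adjusted p = 0.56), with an interval of the difference from 0.08 to 0.76 that is not adjusted for the number of genes.

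Ionotropic glutamate receptor and scaffold genes were higher with desipramine in sham in 31 of 39 (camera adjusted p = 3.21e-05, and adjusted p = 0.263 with an estimated correlation), with the postsynaptic scaffold gene Shank1 at 0.55 ± 0.19. Neurotrophin and activity-dependent peptide genes were higher in 19 of 27, with 1 past the threshold adjusted over the list alone (camera adjusted p = 0.00361, and adjusted p = 0.0693 with an estimated correlation), and Bdnf differed by 1.46 ± 0.75. The score of this list ran from -0.27 to 0.55 between the sham desipramine libraries and moves with the cortical excitatory neuron score, which was 1.28 and 1.57 in replicates 1 and 3, with Bdnf at 16.5 and 15.3 CPM, and -0.85 in replicate 4, with Bdnf at 0.965 CPM. Opioid peptide and receptor genes were higher in 17 of 24 (camera adjusted p = 0.00822, and adjusted p = 0.0693 with an estimated correlation). All 24 oligodendrocyte and myelin markers were lower (camera adjusted p = 4.13e-08, and adjusted p = 0.604 with an estimated correlation), but their score ran from -0.49 to 0.22 between the desipramine libraries and from -0.08 to 0.22 between the saline ones. With edgeR 0 genes passed, 1810 were at an unadjusted p under the threshold, and DESeq2 called 22 genes and limma-voom 0. Leaving out sham desipramine replicate 4, sham saline replicate 2 or sham saline replicate 5 gave 2 genes.

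In SNI, desipramine against saline gave more genes close to the threshold. The integrin gene Itga6 was 0.55 ± 0.10 higher, the kinase regulator gene Trib2 0.54 ± 0.11 higher and Cpeb3, a regulator of local translation, 0.39 ± 0.08 higher, while the clock output gene Dbp was lower at -0.80 ± 0.16 (all adjusted p = 0.0564). Nr1d1, which encodes the clock repressor REV-ERB alpha, was lower at -0.29 ± 0.06 (adjusted p = 0.0732) and Ciart lower at -0.51 ± 0.13 (adjusted p = 0.0881). The neuropeptide gene Gal was 3.79 ± 0.78 higher (adjusted p = 0.0564), Tcf7l2, a marker of thalamic and habenular neurons, 1.32 ± 0.29 higher and the hypothalamic peptide gene Trh 1.41 ± 0.37 higher. Gal ran from 0.185 to 16.2 CPM between the SNI desipramine libraries, with a mean of 7.29 ± 7.79 CPM (SD, n = 4). On saline in SNI its mean was 0.525 ± 0.439 CPM (SD, n = 5), so its fold rests on few counts there.

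Cytosolic ribosomal protein genes were lower in 78 of 79, 33 past the threshold adjusted over the list alone, with a median of -0.17 (camera adjusted p = 1.19e-20, and adjusted p = 0.493 with an estimated correlation). Other lists that mark RNA quality differed in the same groups, with a nuclear long noncoding RNA score of 0.25 ± 0.12 (SD, n = 4) on desipramine and 0.06 ± 0.08 (SD, n = 5) on saline, and a mitochondrial transcript score of 0.31 ± 0.14 (SD, n = 4) and -0.03 ± 0.28 (SD, n = 5). Clock genes were lower in 14 of 19, with 5 lower and 1 higher past it adjusted over the list alone (camera adjusted p = 0.000579, and adjusted p = 0.493 with an estimated correlation). All 24 pan medium spiny neuron markers were lower (camera adjusted p = 6.9e-09, and adjusted p = 0.535 with an estimated correlation). Septal, preoptic and hypothalamic neuron markers were higher in 20 of 23, 6 past it adjusted over the list alone (camera adjusted p = 0.000626, and adjusted p = 0.535 with an estimated correlation). The clock, medium spiny neuron and septal lists move with SNI desipramine replicates 2 and 3, whose septal scores were 1.52 and 1.46, while the ribosomal protein score was -0.11 to -0.07 in the 4 libraries. Without replicates 2 and 3, and also with tissue scores as covariates, 6 of 17 list calls were kept, with that of the ribosomal proteins among them and those of the clock, medium spiny neuron and septal lists lost. With edgeR 0 genes passed, 4148 were at an unadjusted p under the threshold, and DESeq2 called 555 genes and limma-voom 0. Leaving out SNI desipramine replicate 4, the library with the lowest septal score of its group, gave 3352 genes.

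Averaged over both surgeries, desipramine changed 7 genes, with 4 higher and 3 lower. Spred2 rose by 0.25 ± 0.04 (adjusted p = 0.014), Spred3 by 0.35 ± 0.06, Vgf by 0.37 ± 0.07 and the microtubule-associated kinase gene Mast2 by 0.33 ± 0.06 (these 3 at an adjusted p of 0.0277). Dbp fell by 0.73 ± 0.12 (adjusted p = 0.014), Ciart fell by 0.56 ± 0.09 (adjusted p = 0.0191) and Fbxo48, an F-box gene, fell by 0.56 ± 0.09 (adjusted p = 0.0277). Mean Dbp was 71.8 ± 18.8 CPM (SD, n = 4) in sham and 61.4 ± 15.6 CPM (SD, n = 4) in SNI on desipramine, and 112 ± 19.2 CPM (SD, n = 5) and 105 ± 9.31 CPM (SD, n = 5) on saline. In both surgeries each desipramine library had less Dbp than each saline library. For the 4 higher genes, the desipramine and saline libraries overlapped in SNI. There Spred2 ran from 78.3 to 85.8 CPM on desipramine and 67.9 to 84 CPM on saline, and Spred3 from 66.2 to 81.1 and 55.3 to 73.1 CPM. Vgf ran from 219 to 291 and 202 to 226 CPM, and Mast2 from 122 to 177 and 108 to 130 CPM. In sham, of these genes only Spred2 overlapped, at 85.9 to 95.8 and 69 to 88.7 CPM.

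**Figure D2:**
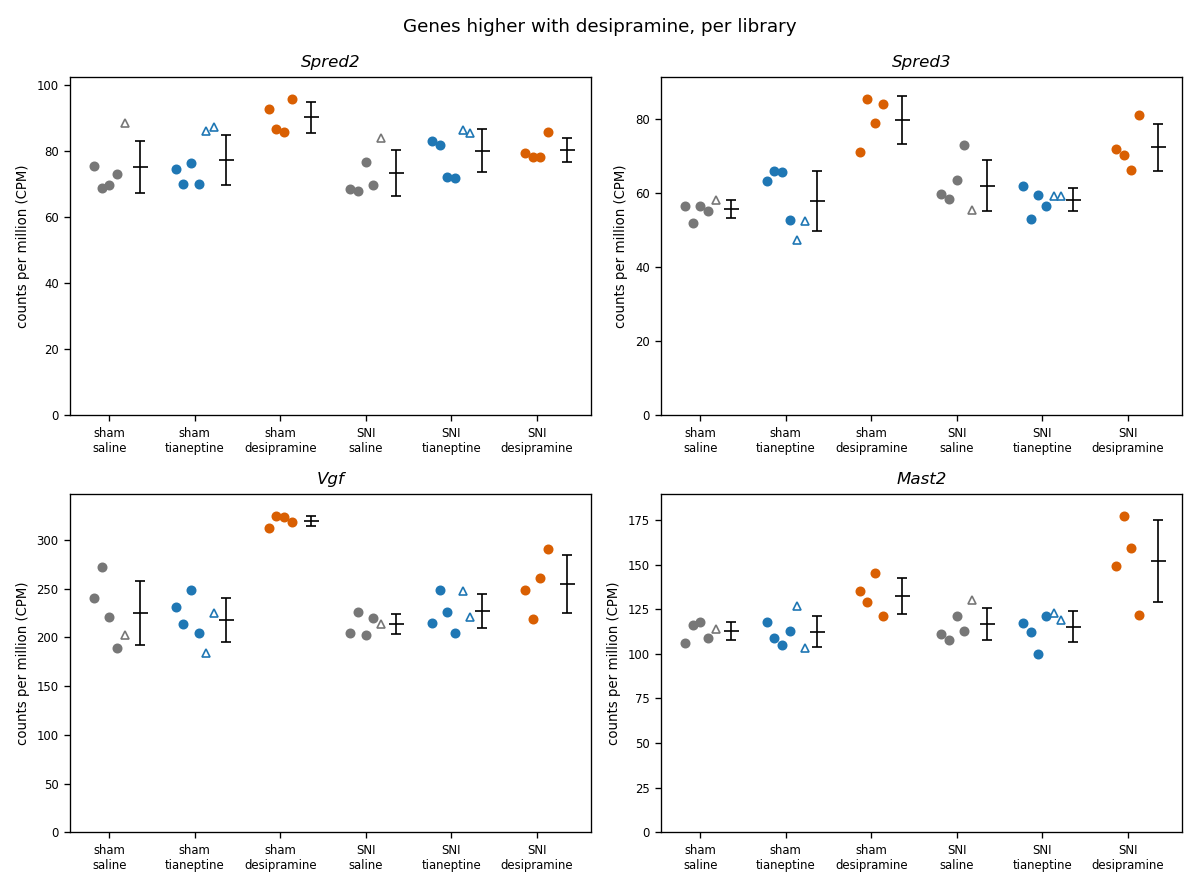
CPM of genes changed by desipramine, averaged over both surgeries, in each library by group, with circles for the first library set, open triangles for the second and bars for mean ± SD. Mean Vgf on desipramine was 319 CPM in sham and 255 CPM in SNI, against 225 and 213 CPM on saline.

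Among the lists, genes that respond to glucocorticoids were lower with desipramine in 23 of 27, averaged over surgeries, 4 past the threshold adjusted over the list alone (camera adjusted p = 4.56e-06, and adjusted p = 0.277 with an estimated correlation). Endoplasmic reticulum stress genes were higher in 20 of 25, 5 past it adjusted over the list alone (camera adjusted p = 5.47e-05, and adjusted p = 0.382 with an estimated correlation), with the chaperone gene Hspa5 at 0.29 ± 0.08. Neurotrophin and activity-dependent peptide genes were higher in 21 of 27, 1 past the threshold over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0173, and adjusted p = 0.277 with an estimated correlation), with Ntrk2, the BDNF receptor gene, at 0.23 ± 0.05. Clock genes were lower in 13 of 19, 2 past the threshold over all genes and 7 adjusted over the list alone (camera adjusted p = 0.000152, and adjusted p = 0.36 with an estimated correlation). Of the 16 list calls of this comparison, 7 were kept without SNI desipramine replicates 2 and 3 and 10 with tissue scores as covariates.

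The count of 7 genes was 0 in replicates 1 to 4 alone and when only the groups compared were fitted, 30 with tissue scores as covariates, 132 with DESeq2 and 154 with 2 surrogate variables. It was 2 without SNI saline replicate 1, 3 without SNI saline replicate 3, sham saline replicate 1, SNI desipramine replicate 1 or sham desipramine replicate 1, 2 or 3, 4 without sham saline replicate 4 or 5, 12 without sham desipramine replicate 4 and 360 without SNI desipramine replicate 4. The test of whether desipramine acted differently in SNI and sham gave 0 genes with edgeR, 2916 at an unadjusted p under the threshold, 100 with DESeq2 and 0 with limma-voom. It gave 957 genes without SNI desipramine replicate 4 and 20 without sham saline replicate 2. The smallest p values there belonged to Npy, the neuropeptide Y gene, at -1.08 ± 0.23, the lactate dehydrogenase gene Ldha at -0.65 ± 0.14 and Rora, a clock activator gene, at 0.73 ± 0.16 (all adjusted p = 0.227).

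The 2 drugs were compared directly in each surgery group, tianeptine at 30 mg/kg and desipramine at 15 mg/kg, so the doses differ. In sham mice 17 genes differed, with 6 higher and 11 lower on tianeptine, and clock genes led them. Ciart was 1.17 ± 0.13 higher on tianeptine (adjusted p = 3.8e-05), with 11 ± 1.01 CPM (SD, n = 6) against 4.92 ± 0.68 CPM (SD, n = 4). Nr1d2 was 0.49 ± 0.08 higher (adjusted p = 0.0106), Dbp 0.80 ± 0.16 higher (adjusted p = 0.048) and Arntl lower at -0.66 ± 0.12 (adjusted p = 0.0267). For each of these 4 genes, all 6 tianeptine libraries lay on the same side of all 4 desipramine libraries. Of 19 clock genes, 13 were higher, with 3 higher and 1 lower past the threshold over all genes and 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00871, and adjusted p = 0.489 with an estimated correlation).

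Spred2 and Etv5, genes tied to the ERK pathway, were also lower on tianeptine than on desipramine in sham mice. Spred2 differed by -0.30 ± 0.05 (adjusted p = 0.013) and Etv5, a transcription factor gene that ERK signalling induces, by -0.60 ± 0.11 (adjusted p = 0.0267). Mean Etv5 was 60.5 ± 7.91 CPM (SD, n = 6) on tianeptine and 87 ± 5.37 CPM (SD, n = 4) on desipramine. Vgf was lower at -0.54 ± 0.09 (adjusted p = 0.011), Calr, an endoplasmic reticulum chaperone gene, lower at -0.40 ± 0.06 (adjusted p = 0.0106) and Kdr lower at -0.78 ± 0.14 (adjusted p = 0.013). Atp6v0a1, a subunit gene of the proton pump of vesicles, was lower at -0.25 ± 0.05 (adjusted p = 0.0378) and Fmnl1, a formin gene, lower at -0.71 ± 0.14 (adjusted p = 0.0395). Blm, a DNA helicase gene, was 0.44 ± 0.08 higher and the zinc finger gene Zfp607a 0.76 ± 0.13 higher. Endothelial markers were lower in 16 of 18, 1 past the threshold over all genes and 5 adjusted over the list alone (camera adjusted p = 1.28e-07, and adjusted p = 0.458 with an estimated correlation). Glutamate receptor and scaffold genes were lower in 31 of 39 (camera adjusted p = 1.24e-05, and adjusted p = 0.261 with an estimated correlation).

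**Figure D3:**
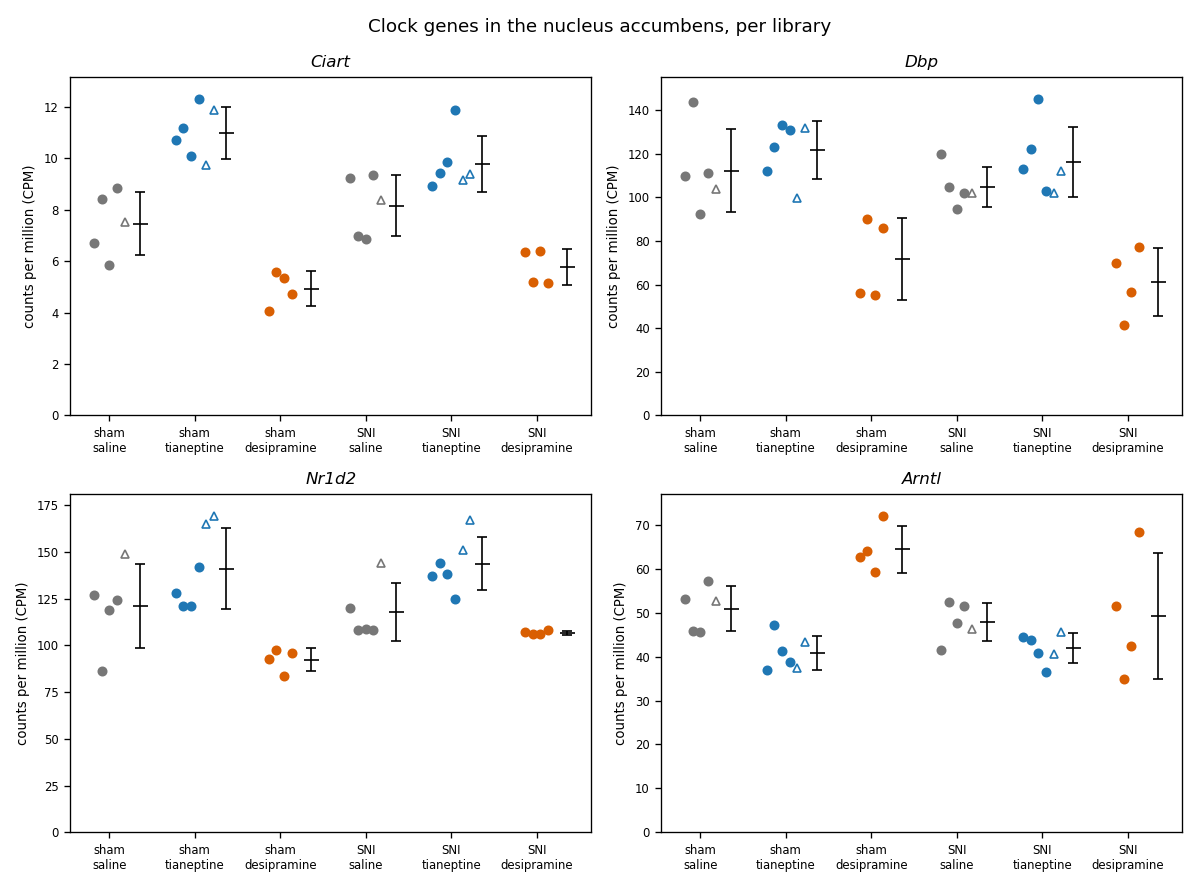
CPM of clock genes in each library by group, with circles for the first library set, open triangles for the second and bars for mean ± SD. In sham mice the 6 tianeptine libraries hold 9.73 to 12.3 CPM of Ciart and the 4 desipramine libraries 4.05 to 5.57 CPM.

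The sham count of 17 genes was 152 with DESeq2, 42 with 2 surrogate variables, 37 with tissue scores as covariates, 9 without sham tianeptine replicates 1 and 6, 1 in replicates 1 to 4 alone and 0 when only these groups were fitted. It was 4 without sham desipramine replicate 2, 6 without sham desipramine replicate 1 or sham tianeptine replicate 4, 8 without sham tianeptine replicate 1 or 2, 10 without sham desipramine replicate 3 and 38 without sham desipramine replicate 4.

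In SNI mice 315 genes differed between the drugs, with 76 higher and 239 lower on tianeptine, 87 of them predicted models. Clock genes again had the smallest p values. Ciart was 0.77 ± 0.13 higher and Dbp 0.96 ± 0.16 higher on tianeptine (both adjusted p = 0.0147), with Dbp at 116 ± 15.9 CPM (SD, n = 6) against 61.4 ± 15.6 CPM (SD, n = 4). Nr1d1 was 0.33 ± 0.06 higher (adjusted p = 0.0195), the clock output gene Tef 0.55 ± 0.11 higher (adjusted p = 0.0196) and Per1, a core clock repressor gene that also responds to light and stress, 0.66 ± 0.17 higher (adjusted p = 0.0483). Of 19 clock genes, 15 were higher, with 7 higher and 1 lower past the threshold over all genes and 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.51e-07, and adjusted p = 0.164 with an estimated correlation). The fry test of the clock list, which does not compare it with other genes, had an adjusted p of 0.000516. Fry values of the other lists in this comparison, and of the clock list in other comparisons, are not reported here. This value alone thus does not set the clock list apart from other lists. The clock score ran from -0.56 to -0.03 between the SNI desipramine libraries, lowest in replicate 2, and with tissue scores as covariates the median size of the 8 called clock genes went from 0.55 to 0.42, with 2 still called.

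Of the 315 genes that passed in SNI, 239 were lower on tianeptine, a lean not kept in the FPKM table or without 1 library: 139 of 268 were lower on log2 FPKM with a pseudocount of 1, 111 of 247 with 0.1, and 2453 of 4825 without SNI desipramine replicate 4. Asic2, an acid-sensing ion channel gene, was lower at -0.82 ± 0.16 and the glycosyltransferase gene Galntl6 lower at -0.94 ± 0.18 (both adjusted p = 0.0195). Kcnj10, the potassium channel gene of astrocytes, was lower at -0.75 ± 0.17, Gal lower at -3.44 ± 0.77 and Lhx9, a transcription factor gene of the thalamus and hypothalamus, lower at -2.63 ± 0.54. Npas1, a marker of pallidal neurons, was lower at -1.36 ± 0.31, Tcf7l2 lower at -1.22 ± 0.29 and Slc6a11, a GABA transporter gene, lower at -1.13 ± 0.29 (adjusted p = 0.0486). Calr was lower at -0.28 ± 0.06 (adjusted p = 0.0376), Kdr lower at -0.54 ± 0.14 and Mast2 lower at -0.43 ± 0.08. Among genes higher on tianeptine, Narf was 0.33 ± 0.06 higher, Mxi1, an antagonist of MYC, 0.31 ± 0.06 higher and Igfbp4, an insulin-like growth factor binding protein gene, 0.91 ± 0.19 higher.

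Septal, preoptic and hypothalamic markers were lower on tianeptine than on desipramine in SNI in 17 of 23, 3 past the threshold over all genes and 8 adjusted over the list alone (camera adjusted p = 0.00411, and adjusted p = 0.596 with an estimated correlation). All 24 pan medium spiny neuron markers were higher, with none past it over all genes (camera adjusted p = 3.82e-10, and adjusted p = 0.554 with an estimated correlation). Both move with SNI desipramine replicates 2 and 3, whose medium spiny neuron scores were -2.22 and -0.8. Glucocorticoid-responsive genes were higher in 21 of 27, 1 past the threshold over all genes and 11 adjusted over the list alone (camera adjusted p = 3.37e-06, and adjusted p = 0.29 with an estimated correlation). Immediate early genes were higher in 28 of 31, 1 past it over all genes and 4 adjusted over the list alone (camera adjusted p = 3.37e-06, and adjusted p = 0.554 with an estimated correlation). Heat shock and chaperone genes were lower in 16 of 17, 5 past it adjusted over the list alone (camera adjusted p = 0.000203, and adjusted p = 0.554 with an estimated correlation). Without SNI desipramine replicates 2 and 3, and also with tissue scores, 7 of 17 list calls were kept, with the clock, glucocorticoid and immediate early lists among them and the septal, medium spiny neuron and heat shock lists lost. Lists that mark RNA quality differed between these groups too. The nuclear long noncoding RNA score ran from -0.29 to 0.08 on tianeptine and from 0.1 to 0.4 on desipramine. The mitochondrial transcript score was -0.04 ± 0.47 (SD, n = 6) and 0.31 ± 0.14 (SD, n = 4).

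The SNI count of 315 genes was 1247 with DESeq2, 101 with limma-voom, 79 without a filter, 605 without the library set term, 33 with 2 surrogate variables, 27 in replicates 1 to 4 alone, 4 with tissue scores as covariates and 0 when only these groups were fitted. It was 0 without SNI desipramine replicate 2, 3 or both, or SNI tianeptine replicate 2 or 3, 58 without SNI desipramine replicate 1, 4825 without SNI desipramine replicate 4, and 91, 48 and 641 without SNI tianeptine replicate 1, 5 and 6.

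**Figure D4:**
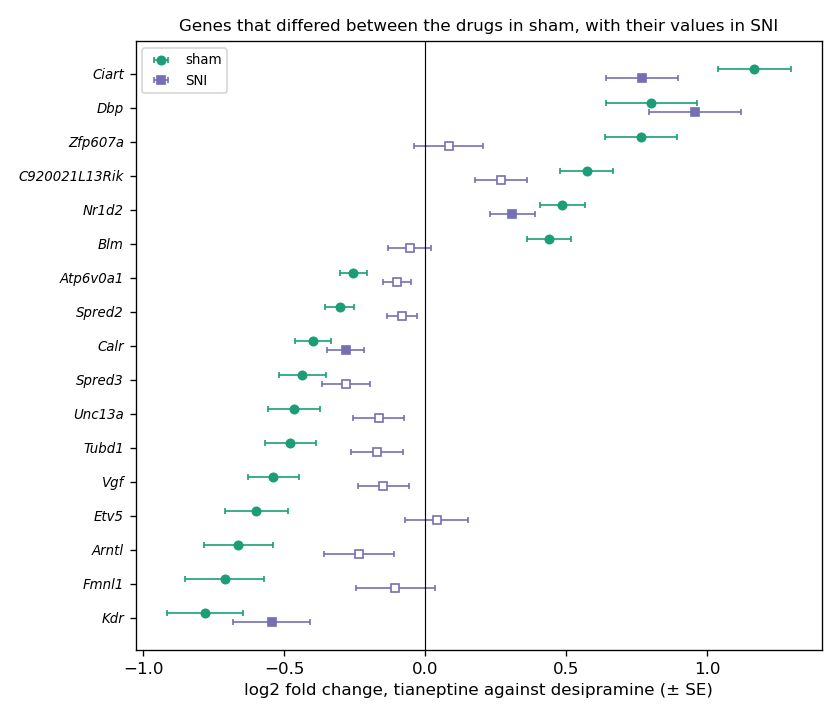
Log2 fold change of tianeptine against desipramine, with SE, in sham and in SNI for the 17 genes called in sham, with filled symbols where the adjusted p is below the threshold. Ciart, Dbp, Nr1d2, Calr and Kdr are called in both, and 15 of the 17 have the same sign.

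Of the 17 genes called in sham, 15 had the same sign in SNI and 5 were called in both, namely Ciart, Dbp and Nr1d2, higher on tianeptine, and Calr and Kdr, lower. If the calls were independent, 0.0192 higher and 0.111 lower genes would be expected in both. The libraries of the sham and SNI comparisons do not overlap. Of the 315 genes called in SNI, 150 had the same sign in sham. Across all genes, which are not independent replicates, the drug differences in SNI and sham had an r of -0.145, where simulated groups with no change gave -0.419 to 0.472.

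The receptor genes Oprm1, Adra2a, Drd1 and Drd2 did not pass between the drugs, whose doses differ. In SNI the difference in Oprm1 was 0.01, with an interval from -0.32 to 0.34, and in sham it was -0.31, with an interval from -0.64 to 0.02. In sham, mean Oprm1 was 62.8 ± 22.9 CPM (SD, n = 5) on saline, 69 ± 12.5 CPM (SD, n = 6) on tianeptine and 78.3 ± 12.5 CPM (SD, n = 4) on desipramine. In SNI it was 75.3 ± 12 CPM (SD, n = 5) on saline, 77.8 ± 9.06 CPM (SD, n = 6) on tianeptine and 70.8 ± 8.02 CPM (SD, n = 4) on desipramine. For Adra2a, the alpha-2A adrenoceptor gene, the difference was -0.28 in SNI, from -1.44 to 0.88, and -0.45 in sham, from -1.61 to 0.71. For Drd1 it was 0.70 in SNI, from -0.08 to 1.48, and for Drd2 0.62, from -0.09 to 1.33. In sham, Drd1 differed by 0.10, from -0.67 to 0.86, and Drd2 by -0.05, from -0.75 to 0.65. Bdnf differed by -2.16 in sham, from -3.73 to -0.60 (adjusted p = 0.282), and by -0.18 in SNI, from -1.71 to 1.35. Its level moves with the cortical score, as in sham desipramine replicate 3 (15.3 CPM, score 1.57), sham tianeptine replicate 5 (11.7 CPM, score 1.46) and SNI saline replicate 5 (14.3 CPM, score 1.60), and with tissue scores as covariates the sham difference was -0.48 (adjusted p = 0.358). The AMPA receptor gene Gria1 differed by 0.07 in SNI, from -0.13 to 0.27, and Fos by 0.97, from -0.22 to 2.16.

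SNI mice on each drug were also compared with sham mice on saline, the control of the design, so these groups differ in both surgery and drug. SNI mice on desipramine differed in 2640 genes, with 1810 higher and 830 lower, 567 of them predicted models. The lean to higher genes was smaller with 1500 and 1009 by limma-voom, 1465 and 1225 on log2 FPKM with a pseudocount of 0.1, and 3250 and 3122 without SNI desipramine replicate 4. Gal was 5.12 ± 0.86 higher, Lhx5, a transcription factor gene of the septum and hypothalamus, 4.50 ± 0.77 higher, Tcf7l2 1.68 ± 0.29 higher and Slc6a11 1.58 ± 0.29 higher (all adjusted p = 0.0093). Mean Gal in sham saline was 0.185 ± 0.188 CPM (SD, n = 5), so the size of its fold rests on few counts there. The insulin receptor substrate gene Irs4, found in the hypothalamus, was 3.61 ± 0.83 higher (adjusted p = 0.0124), Prlr, the prolactin receptor gene, 3.75 ± 0.91 higher (adjusted p = 0.0148) and Calb2, the calretinin gene, 2.01 ± 0.46 higher (adjusted p = 0.0123). Among opioid genes, Oprl1, the nociceptin receptor gene, was 0.62 ± 0.16 higher (adjusted p = 0.0206) and Pnoc, the nociceptin precursor gene, 1.90 ± 0.55 higher (adjusted p = 0.03). The serotonin receptor gene Htr7 was 1.44 ± 0.36 higher and the peptide gene Trh 1.16 ± 0.37 higher.

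Lower genes in that comparison included Dbp at -0.89 ± 0.16, Mxi1 at -0.34 ± 0.06 (both adjusted p = 0.0093), the cell cycle inhibitor gene Cdkn1a at -0.79 ± 0.16 (adjusted p = 0.0104) and Nrgn, a calmodulin-binding gene of forebrain neurons, at -1.15 ± 0.26 (adjusted p = 0.0123). The meningeal transporter genes Slc22a6 and Slc13a4 were lower at -3.77 ± 1.09 and -3.31 ± 0.97, and the glucocorticoid-induced genes Sgk1 and Klf9 at -0.53 ± 0.16 and -0.54 ± 0.15. Drd1 at -0.88 ± 0.39 and Drd2 at -0.91 ± 0.35 did not pass. Septal, preoptic and hypothalamic markers were higher in 21 of 23, 13 past the threshold over all genes and 14 adjusted over the list alone, where 1 other was lower (camera adjusted p = 8.7e-06, and adjusted p = 0.516 with an estimated correlation). All 24 medium spiny neuron markers were lower, 1 past it over all genes and 13 adjusted over the list alone (camera adjusted p = 1.29e-11, and adjusted p = 0.516 with an estimated correlation). All 20 fibroblast and meninges markers were lower, 8 past it over all genes and 19 adjusted over the list alone (camera adjusted p = 8.7e-06, and adjusted p = 0.516 with an estimated correlation). These lists move with SNI desipramine replicates 2 and 3, with septal scores of 1.52 and 1.46, and with sham saline replicate 3, with a fibroblast score of 2.72. Lists that mark RNA quality differed as well. The nuclear long noncoding RNA score was 0.25 ± 0.12 (SD, n = 4) in SNI desipramine and -0.09 ± 0.13 (SD, n = 5) in sham saline. The mitochondrial transcript score was 0.31 ± 0.14 (SD, n = 4) and -0.11 ± 0.54 (SD, n = 5).

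The count of 2640 genes was 1 without SNI desipramine replicate 2, 7 without replicate 3, 6372 without replicate 4, 1503 without sham saline replicate 2 and 1712 without sham saline replicate 4. It was 1387 in replicates 1 to 4 alone, 1327 without a filter, 1 with 2 surrogate variables, and 0 with tissue scores as covariates, without SNI desipramine replicates 2 and 3 together, without sham saline replicates 2 and 3 together, or when only these groups were fitted, with tissue scores Oprl1, Pnoc, Htr7 and Irs4 changed sign, and without SNI desipramine replicates 2 and 3 Trh turned to -0.38.

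SNI mice on tianeptine against sham mice on saline gave 0 genes with edgeR, 1831 at an unadjusted p under the threshold, and 0 with DESeq2 and limma-voom. The interferon-induced GTPase genes Iigp1 and Gbp4 differed by -1.91 ± 0.49 and -2.24 ± 0.58, Lamc1 by -0.26 ± 0.07, Kdr by -0.46 ± 0.12 and Cldn5 by -0.55 ± 0.15 (all adjusted p = 0.634). Interferon response genes were lower in 31 of 34, 9 past the threshold adjusted over the list alone (camera adjusted p = 9.7e-08, and adjusted p = 0.608 with an estimated correlation). Endothelial markers were lower in 17 of 18, 5 past it adjusted over the list alone (camera adjusted p = 4.96e-08, and adjusted p = 0.608 with an estimated correlation). The interferon score was 0.98 in sham saline replicate 3, the highest of its group. Without sham saline replicates 2 and 3, 3 of 15 list calls were kept, the interferon response list turned to higher (adjusted p = 0.234) and the endothelial list no longer passed (adjusted p = 0.179), and with tissue scores 7 of 15 were kept, both of these among them.

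The drug effects in SNI were set against the effect of SNI itself across all genes, to ask whether a drug moved genes back towards sham. With tianeptine, r was -0.388, but the saline SNI libraries enter both effects, and simulated groups with no change gave a mean r of -0.511, from -0.79 to -0.18. With the saline libraries split so that none was used in both effects, the mean r was 0.032, from -0.212 to 0.492. With desipramine, r was 0.139, where simulated groups with no change gave a mean r of -0.47, from -0.785 to -0.131, and 0.267 with split libraries, from 0.025 to 0.593. Tissue scores step the same way from sham saline to SNI saline to SNI desipramine. Mean septal scores were -0.47, -0.01 and 0.81, cortical scores 0.45, -0.09 and -0.79, and medium spiny neuron scores 0.29, -0.04 and -0.74. Tissue makeup alone could thus give a positive r, also with split libraries, so this r cannot be read as a drug effect. The effects of the 2 drugs against saline, at doses that differ, had an r of 0.077 in SNI and 0.259 in sham. Simulated groups with no change, which share the saline libraries too, gave a mean r of 0.457, from 0.028 to 0.797, and 0.436, from -0.023 to 0.752. With split saline libraries the mean r was -0.191 and -0.116.

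In mm10, Ciart (ENSMUSG00000038550.10) lies on chromosome 3 from 95878503 to 95882251, Dbp (ENSMUSG00000059824.12) on chromosome 7 from 45705088 to 45710203 and Nr1d2 (ENSMUSG00000021775.11) on chromosome 14 from 18204054 to 18239127. Arntl (ENSMUSG00000055116.8) lies on chromosome 7 from 113207465 to 113314126 and Spred2 (ENSMUSG00000045671.17) on chromosome 11 from 19924375 to 20024026. Spred3 (ENSMUSG00000037239.8) lies on chromosome 7 from 29158829 to 29170411 and Vgf (ENSMUSG00000037428.14) on chromosome 5 from 137026392 to 137033351. Calr (ENSMUSG00000003814.8) lies on chromosome 8 from 84841850 to 84846934, Kdr (ENSMUSG00000062960.10) on chromosome 5 from 75932827 to 75978458 and Oprm1 (ENSMUSG00000000766.18) on chromosome 10 from 6758506 to 7038198.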

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

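Of the tests in this part, those on the levels of Ciart, Dbp, Nr1d2, Arntl, Spred2, Spred3, Vgf, Mast2, Kdr, Calr and Gal were chosen after the result was seen, and the others were planned. A library is named here where the gap to its nearest neighbour takes more of its group's range than Dixon's test allows. This held in 12 of 234 groups, where chance gives about 12.

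The D2 medium spiny neuron score was -0.362 in SNI tianeptine replicate 4, against 0.097 to 0.274 in the others of its group. In sham tianeptine replicate 5 the oligodendrocyte precursor score was 0.063, against -0.118 to -0.07. The dorsal striatum score was 0.686 in sham tianeptine replicate 6, against -0.187 to 0.116. Ciart, a clock gene, was at 11.9 CPM in SNI tianeptine replicate 4, against 8.91 to 9.86 CPM. Spred2 was at 85.8 CPM in SNI desipramine replicate 4, against 78.3 to 79.5 CPM, and Oprm1 in the same library at 82.8 CPM, against 66 to 67.8 CPM. Adra2a reached 19.7 CPM in sham saline replicate 3, against 5.27 to 8.93 CPM. Bdnf reached 11.7 CPM in sham tianeptine replicate 5, against 0.877 to 4.15 CPM, and 14.3 CPM in SNI saline replicate 5, against 1.01 to 4.46 CPM. Gria1 was at 1150 CPM in sham desipramine replicate 4, against 988 to 1010 CPM. The total count was 120.7 M in sham saline replicate 5, against 24.5 to 36 M, and 98 M in SNI saline replicate 5, against 27.5 to 33.1 M, both in the second library set.

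Gene lists also differed between SNI and sham in their response to a drug, by the interaction of drug and surgery. Camera called 15 lists for tianeptine and 14 for desipramine, and 0 with an estimated correlation, while the same interactions called 0 genes with edgeR, with 997 and 2916 at an unadjusted p under the threshold. Leaving out sham saline replicates 2 and 3 kept 7 of the 15 calls for tianeptine, leaving out SNI desipramine replicates 2 and 3 kept 6 of the 14 for desipramine, and tissue scores as covariates kept 11 and 7. These alternatives were chosen after the result was seen. A positive median below means a higher response in SNI than in sham. The same SNI saline and sham saline libraries enter both interactions, so a list called for both drugs is not called independently. A high score in sham saline alone also gives a positive median. The mean interferon score was 0.26 in sham saline, up to 0.98 in 1 library, and -0.08 in SNI saline. On tianeptine it was -0.06 in sham and -0.07 in SNI, and on desipramine -0.05 and 0.02.

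For tianeptine, vessel and support cell lists had the smallest p values: endothelial markers (median log2 0.40, camera adjusted p = 4.43e-13), mural cells (0.42, adjusted p = 1.7e-09) and fibroblasts and meninges (1.45, adjusted p = 1.69e-07). Immune lists were interferon response genes (0.40, adjusted p = 2.01e-05), cytokines (0.25, adjusted p = 5.58e-05), peripheral immune cells (0.87, adjusted p = 0.0033) and microglia (0.10, adjusted p = 0.00808). Choroid plexus and ependyma markers (-1.85, adjusted p = 3.29e-05) and septal, preoptic and hypothalamic markers (-0.57, adjusted p = 0.0144) had negative medians. Neuronal lists were pan medium spiny neuron markers (0.30, adjusted p = 0.00296) and immediate early genes (0.31, adjusted p = 0.0144). The rest were oxidative phosphorylation (-0.09, adjusted p = 2.95e-08), ribosomal proteins (-0.05, adjusted p = 0.000389), nuclear long noncoding RNAs (-0.12, adjusted p = 0.00794) and extracellular matrix genes (0.13, adjusted p = 0.000852). With an estimated correlation the adjusted p values of these lists ran from 0.261 to 0.845.

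For desipramine, glial lists had positive medians: oligodendrocytes and myelin (0.38, camera adjusted p = 3.9e-06), their precursors (0.22, adjusted p = 0.00538) and astrocytes (0.40, adjusted p = 6.01e-06). Cholinergic interneuron markers (1.13, adjusted p = 6.47e-05), septal markers (0.49, adjusted p = 0.0362), interferon response genes (0.51, adjusted p = 8.17e-05), endothelial markers (0.30, adjusted p = 0.00503) and extracellular matrix genes (0.27, adjusted p = 0.00467) were also positive. Negative medians belonged to pan medium spiny neuron markers (-0.30, adjusted p = 8.75e-05), cortical excitatory neuron markers (-1.03, adjusted p = 0.033), immediate early genes (-0.41, adjusted p = 0.000882), glutamate receptor and scaffold genes (-0.22, adjusted p = 0.00457), ribosomal proteins (-0.13, adjusted p = 7.14e-11) and red blood cell genes (-0.55, adjusted p = 0.0341). With an estimated correlation their adjusted p values ran from 0.623 to 0.74.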

How the results depend on the processing

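The alternatives with tissue scores and those that leave out pairs of libraries were chosen after seeing the data, and the cause of each move below was not tested unless it is named. Counts of genes changed that are not given for an alternative stayed within 1.5 times their value. Of 29639 values of named genes over all alternatives, 27345 kept their side of the threshold, 1731 lost it, 558 gained it and 5 reversed after passing. In all, 284 changed sign, these 5 among them. A value that passed neither in the main test nor in the alternative counts as kept, so the share kept does not measure how firm the calls are. Fitting only the groups compared kept 921 of 1084 values and lost 163, although no gene passed there in the comparisons that had calls. Without SNI desipramine replicates 2 and 3, 150 of 512 values lost the threshold. With an estimated correlation the list calls went from 197 to 0. With tissue scores as covariates, the calls kept were 10 of 20 for SNI desipramine against sham saline, 10 of 16 for desipramine averaged, 7 of 14 for tianeptine averaged and 11 of 19 between the drugs in sham. Without SNI desipramine replicates 2 and 3, 14 of 20 and 7 of 16 of the first 2 were kept, and without sham saline replicates 2 and 3, 7 of 14 for tianeptine averaged.

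With DESeq2 size factors, desipramine against saline in sham gave 2 genes. The DESeq2 Wald test gave 1 for SNI against sham on saline, 1 for tianeptine in SNI, 1 for tianeptine in sham, 1 for tianeptine averaged over surgeries, 555 for desipramine in SNI, 22 for desipramine in sham, 132 for desipramine averaged, 100 for its interaction with surgery, and 1247 in SNI and 152 in sham between the drugs. Limma-voom gave 101 between the drugs in SNI. Without a filter this count was 79 and that of SNI desipramine against sham saline 1327, with more genes tested. The stricter filter gave 1 for desipramine in sham. Without the library set term the drugs differed in 605 genes in SNI.

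Replicates 1 to 4 alone, which are fewer libraries, gave 27 between the drugs in SNI, 1 in sham, 1387 for SNI desipramine against sham saline and 0 for desipramine averaged. Fitting only the groups compared, with fewer residual degrees of freedom, gave 0 for each of these 4. With 2 surrogate variables the counts were 23 for desipramine in SNI, 22 for it in sham, 154 for it averaged, 33 and 42 between the drugs in SNI and sham, 1 for SNI desipramine against sham saline and 1 for tianeptine averaged. Desipramine in SNI gave 1 gene on log2 FPKM with a pseudocount of 1 and 13 with 0.1.

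With tissue scores as covariates the counts were 15 for desipramine in sham, 30 for it averaged, 4 and 37 between the drugs in SNI and sham, and 0 for SNI desipramine against sham saline. In that last comparison Oprl1 turned to -0.014, Pnoc to -0.181, Htr7 to -0.063 and Irs4 to -0.235. Without SNI desipramine replicates 2 and 3, the drugs differed in 0 genes in SNI, SNI desipramine and sham saline in 0, with Trh reversed to -0.38, and desipramine averaged in 4. Without sham saline replicates 2 and 3, the counts were 1 for desipramine in sham, 3 for its interaction and 0 for SNI desipramine against sham saline. There 8 of the 11 lists called for desipramine in sham kept their call, 20 were called, and the interferon response list reversed past the threshold, from lower (adjusted p = 1.68e-05) to higher (adjusted p = 0.0292). Without sham tianeptine replicates 1 and 6, the drugs differed in 9 genes in sham.

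The replicate numbers do not pair animals across groups: 67 pairs of libraries with the same number had a mean correlation of residuals of -0.037, and pairs with different numbers 0.008. With the replicate number as a block the counts were 41 and 11 between the drugs in SNI and sham and 4 for desipramine averaged. With split saline libraries, which removes the shared libraries that tie the effects together, the correlation of the SNI effect with that of tianeptine turned to 0.032, and that of the drugs' effects to -0.191 in SNI and -0.116 in sham.

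With each library left out in turn, counts ran from 0 to 3352 for desipramine in SNI, 0 to 2 for it in sham, 2 to 360 for it averaged and 0 to 957 for its interaction. Between the drugs they ran from 0 to 4825 in SNI and 4 to 38 in sham, and from 1 to 6372 for SNI desipramine against sham saline. List calls ran from 177 to 207, and each remaining count of 0 stayed at 0. The highest counts came without SNI desipramine replicate 4, except that of desipramine in sham, which was 2 without sham desipramine replicate 4 or sham saline replicate 2 or 5, and that between the drugs in sham, which came without sham desipramine replicate 4. The lowest came without SNI desipramine replicate 2 for SNI desipramine against sham saline, sham desipramine replicate 2 between the drugs in sham, SNI saline replicate 1 for desipramine averaged, and SNI desipramine or SNI tianeptine replicate 2 or 3 between the drugs in SNI.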

Other observations

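Of the tests in this part, the splits of the libraries, the second library set for the 2640 genes, tissue for the clock genes and for the 4 desipramine genes, the time of day of collection, the comparison of the 4 genes with tianeptine, the clock phase scores and every value with tissue scores as covariates were chosen after the result was seen. The list of ERK pathway targets was also made after the rise of Spred2 and Spred3 had been seen, though its bounds were set before it was tested.

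Some chaperone, cholinergic and GABA genes were also higher in SNI mice on desipramine than in sham mice on saline, with list calls that were lost with an estimated correlation. Heat shock and chaperone genes were higher in 15 of 17, 6 past the threshold over all genes (camera adjusted p = 0.0004, and adjusted p = 0.516 with an estimated correlation). Stip1, a co-chaperone of HSP70 and HSP90, rose by 0.43 ± 0.10 (adjusted p = 0.0123) and Hsp90aa1 by 0.37 ± 0.11 (adjusted p = 0.0285). Markers of cholinergic interneurons were higher in 9 of 10, 5 past the threshold over all genes (camera adjusted p = 0.000714, and adjusted p = 0.516 with an estimated correlation). Among them, Lhx8, a transcription factor of forebrain cholinergic neurons, rose by 2.06 ± 0.55 and Ache, the acetylcholinesterase gene, by 0.80 ± 0.19. GABA system genes were higher in 17 of 23, with 9 higher and 1 lower past the threshold over all genes (camera adjusted p = 0.00984, and adjusted p = 0.516 with an estimated correlation). Slc6a13, a GABA transporter gene of meninges, fell by 1.99 ± 0.62. These lists move with SNI desipramine replicates 2 and 3, whose septal scores were 1.52 and 1.46, and without them the heat shock and chaperones list no longer passed (adjusted p = 0.109), nor did it with tissue scores as covariates (adjusted p = 0.313).

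Against SNI saline, markers of glia were higher in part of the desipramine libraries: the astrocyte score ran from -0.05 to 0.55 and the oligodendrocyte precursor score from -0.12 to 0.40 between them, both highest in replicate 2, whose medium spiny neuron score was -2.22. Astrocyte markers were higher in 17 of 20, 1 past the threshold adjusted over the list alone (camera adjusted p = 0.00125, and adjusted p = 0.535 with an estimated correlation), with Fgfr3 at 0.39 ± 0.09 (adjusted p = 0.0769). Oligodendrocyte precursor markers were higher in 12 of 14, 5 past it adjusted over the list alone (camera adjusted p = 0.000401, and adjusted p = 0.493 with an estimated correlation), with Cspg4 at 0.37 ± 0.09 (adjusted p = 0.0868). Both list calls were lost without SNI desipramine replicates 2 and 3 and with tissue scores as covariates. Averaged over surgeries, cholesterol synthesis genes were higher with desipramine in 22 of 25 (camera adjusted p = 0.00155, and adjusted p = 0.592 with an estimated correlation), a call lost under the same alternatives. In sham mice all 6 red blood cell genes were higher with desipramine (camera adjusted p = 0.00109, and adjusted p = 0.296 with an estimated correlation). Between the drugs in sham, cortical excitatory neuron markers were lower on tianeptine in 20 of 25 (camera adjusted p = 0.000117, and adjusted p = 0.509 with an estimated correlation) and myelin markers higher in 22 of 24 (camera adjusted p = 0.000148, and adjusted p = 0.637 with an estimated correlation). In SNI against sham on saline, ribosomal protein genes were higher in 71 of 79, with a median of 0.06 (camera adjusted p = 6.64e-07, and adjusted p = 0.67 with an estimated correlation).

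The 2640 genes that differed between SNI mice on desipramine and sham mice on saline include many markers of the septum and hypothalamus. The second, deeper library set does not account for them, since replicates 1 to 4 alone gave 1387 genes. Tissue of neighbouring regions in the punches is a candidate explanation: log2 fold changes predicted from the cortical, septal and medium spiny neuron scores, with slopes from the other 5 groups, correlated with the observed ones at r = 0.831 over the 2625 called genes outside these lists (0.802 to 0.841 with each library of the other groups left out), and at 0.61 over all genes outside them. With the 3 scores as covariates the median size of the change went from 0.55 (SE 0.15) to 0.14 (SE 0.12), 0.253 of its value, and 0 genes passed, with a smaller median change and no larger median error. A drug effect apart from tissue cannot be told apart from none for the part that remains, because the scores are themselves uneven between these groups, which differ in surgery as well.

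Clock genes differed between tianeptine and desipramine in both surgeries. Neighbouring tissue is argued against in sham, where with tissue scores as covariates the median size of the called clock genes was 1.02 times that without, from 0.73 to 0.75, with 4 of 4 still called. In SNI it went from 0.55 to 0.42 with 2 of 8 still called, so a part of the SNI difference may come with tissue. In replicates 1 to 4 alone the ratio was 0.989 in sham and 1.03 in SNI, with 1 of 4 and 4 of 8 still called among fewer libraries. The size of the difference thus does not need the second library set. The ratio is no separate test of that set, because the model already holds a term for it and it has no desipramine library. A drug that shifts or reshapes the local clock, and a different time of day of collection between the groups, cannot be told apart: both predict the signs of 1 phase, seen in 9 of 10 genes in the mean of both surgeries, and the time of collection is not given in the sources used here. The 10 genes include Dbp, Ciart, Nr1d2 and Arntl, already called between the drugs, and Clock matched at a mean of -0.02. The count thus largely restates those calls.

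A score of clock phase, from genes that peak together less those of the opposite phase, holds Dbp, Ciart, Nr1d2 and Arntl, already called between the drugs, so it restates their difference and is no separate test of it. In replicates 1 to 4 in sham it was 0.3 ± 0.11 (SD, n = 4) on tianeptine and -0.53 ± 0.14 (SD, n = 4) on desipramine. Against saline in sham it differed by -0.51 on desipramine (adjusted p = 0.1, exact test over 70 splits) and by 0.31 on tianeptine (adjusted p = 0.133), neither past the threshold. The smallest p this test can give is 0.0286, which desipramine reached before adjustment over 7 tests, so not passing decides little. In SNI the means were 0.25 ± 0.09 and -0.13 ± 0.38 (SD, n = 4 each, adjusted p = 0.16). The SNI desipramine mean rests on scores that differ in sign, 0.35 in replicate 2, the library with a septal score of 1.52, against -0.22, -0.08 and -0.56 in replicates 1, 3 and 4. Among the genes of the opposite phase, Arntl differed between the drugs by -0.66 in sham and -0.23 in SNI, Npas2 by -0.33 and 0.39, and Clock by -0.06 and 0.02, so in SNI Npas2 and Clock do not follow the phase.

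Spred2, Spred3, Vgf and Mast2 rose with desipramine averaged over surgeries. For the 4 genes as a set, tissue is argued against by a ratio of 0.918 of their median with tissue scores as covariates, from 0.34 to 0.31 with 4 still called. In SNI, Mast2 was at 177, 159, 149 and 122 CPM in desipramine replicates 2, 3, 1 and 4, the order of their medium spiny neuron scores, lowest first. Replicate 4 lay within the saline range of 108 to 130 CPM, so tissue stays open for Mast2 in SNI. In replicates 1 to 4 alone the ratio was 1.01, where 0 passed among fewer libraries, so the size does not need the second library set. The model already holds a term for that set, so this ratio is no separate test of it. Odd saline libraries are argued against for the 4 genes as a set, since the median against tianeptine was 1.03 times that against saline. In SNI, mean Spred2 was 80.5 ± 3.57 CPM (SD, n = 4) on desipramine and 80.3 ± 6.51 CPM (SD, n = 6) on tianeptine. These levels, not adjusted for library set, do not argue against that explanation for Spred2 in SNI. A general rise of ERK pathway target genes stays open: 14 other targets had a median log2 fold change of 0.09, with 9 higher, 5 lower and 0 called, so of the 2 bounds set before the test the directional fry test met its own, of 0.05, and the median, at percentile 98.9 of 10000 lists matched in level, missed its own, of 0.1. Greater ERK or neurotrophin signalling under desipramine is therefore a hypothesis, which phosphorylated ERK in the same tissue could test.

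Each count of genes was set against 100 splits of its libraries into groups of the same sizes, the real one included. For the 17 genes between the drugs in sham, 3 of 100 splits, the real one among them, gave as many (highest other 756). The 7 genes with desipramine averaged over surgeries were given by 3 of 100 counted in this way (highest other 617). The 315 genes between the drugs in SNI were given by 5 of 100 (highest other 3415). The 2640 genes of SNI desipramine against sham saline were given by 5 of 100 (highest other 4884). Chance cannot be excluded for any of these counts. The shares are not adjusted for the 13 comparisons, and the splits were chosen after the result was seen. Shares of 3 and 5 of 100 are also too close to set the counts apart. Several of these splits call many times the real count, which points to a structure of the samples. The highest ones in the SNI comparisons keep SNI desipramine replicates 1, 2 and 3 together and put replicate 4 on the other side, and the highest between the drugs in sham does the same with sham desipramine replicates 1, 2 and 3.

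For a count of 0 all 100 of 100 splits are as large whatever the data, so the splits decide nothing there. The highest other count was 1 for SNI against sham on saline, 0 for tianeptine in SNI, 49 for it in sham, 1 for it averaged, 3 for its interaction with surgery and 0 for SNI tianeptine against sham saline. For desipramine it was 79 in sham, 1 for the interaction and 3213 in SNI, again with SNI desipramine replicates 1, 2 and 3 on one side and replicate 4 on the other. The tools and unadjusted counts beside these counts of 0 stand with each comparison.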
